A study of Homo sapiens with 6 samples.

How the data were processed

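RNA of 6 samples of the human leukaemia line Kasumi-1 was compared, 3 kept with control and 3 with I1 at 0.125 µM, each for 48 h. Per the labels' protocols, RNA was isolated with Trizol and made into libraries with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps strand. Per the submitters' processing notes, Trimmomatic, HISAT2, Cufflinks and HTSeq were used with the genome build hg38; their versions and roles, the annotation and the use of strand in counting are not given in the sources used here. The authors deposited 1 table of FPKM values, with 29810 genes by Ensembl identifier and 6 sample columns. The table's own name speaks of other cell lines and another agent, but its 6 column names match the titles of the 6 samples and no others, and the values were used on that ground. Columns not used numbered 0. Symbols were found for 29507 of the identifiers, and 1614 genes were 0 in all libraries.

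FPKM divides reads by gene length and by a library total, so a change in a few abundant genes shifts all others, and short genes reach a high FPKM from few reads. The low values of a gene were whole multiples of a step, which gave the depth. With exon lengths of GENCODE release 29, which matched 29703 genes, 95.9% of these genes (28484) had whole read numbers in all libraries within a tolerance of 0.05 reads. For genes above 0 in all libraries the share was 94.5%, and 0.25% when the lengths were shuffled. The library totals used for scaling, rounded, lay between 17331000 and 18204000 in the controls and between 16391000 and 16948000 with I1, and the reads recovered in genes between 14975000 and 16654000. A read in a kilobase of transcript was worth 0.0549 to 0.0610 FPKM, and a floor of 3 reads 0.165 to 0.183 FPKM. Intervals and floors cover counting error only. Coordinates are 1-based, on hg38 from GENCODE release 29.

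I1 was compared with control by limma 3.58.1 in R 4.3.3 (tables were prepared with Python 3.11.15), on log2(FPKM + 1) with an intensity trend, for 11913 genes with at least 1 FPKM in at least 3 of the 6 libraries. The threshold was a Benjamini-Hochberg adjusted p under 0.05, 2-sided, with a log2 fold change of at least 1 in size. Fold changes on this scale understate those of low genes. Gene lists, 49 in number, covered myeloid differentiation, stem cell and fusion genes, other cell types, the cell cycle, cell death, signalling, stress, metabolism, chromatin and DNA repair; the 41 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 41. The genes named are the 8 with the largest rise and the 8 with the largest fall among those with an adjusted p under 0.05, a mean of at least 5 FPKM, groups that do not overlap and a proper symbol, which only MIR3685 met; per described list up to 2 of the largest rises and 2 of the largest falls past the adjusted p, or, with none, up to 2 members with the highest mean FPKM; and KIT, CD34, RUNX1, RUNX1T1, ITGAM, CD14, CEBPA, SPI1, VEGFA, MYC, CDKN1A and BCL2. The test, the lists, the naming rule and the first set of other settings were fixed before the data were examined. A count test was planned only for a table of counts, which this is not.

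Nothing in the labels says that the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. No replicate pair agreed within counting error (chi-square per degree of freedom 21.5 to 73.3). The titles number the samples 1 to 3 in each group. Deviations from the group means correlated at 0.476, 0.457 and 0.412 between samples of the same number and at -0.348 to -0.0990 between samples of different numbers. Deviations sum to 0 within a group, so the negative values follow from the positive ones and are no separate evidence. On the positive values the numbers were taken to pair the samples. The fit with the replicate number as a block is given where it changes a call.

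The fit was tested on simulated data, read counts drawn for 11050 genes from the means and spread of these libraries. For I1 against control with 200 changed genes in each of 5 simulations, 96.8% of genes changed 4-fold and 27.1% of those changed 2-fold were recovered (55.9% of the latter by adjusted p alone), with 8.2 false calls per simulation. The changed genes were drawn from those with a mean of at least 100 reads, so this recovery does not cover genes with few reads. The simulated samples held no pairing and no trend with GC content. With no changed gene there were 0.4 calls per simulation, and 2.4 with the block. Of the simulated lists, 10 of 10 shifted by 0.3 on the log2 scale and 0 of 30 unshifted ones were called. Their members were picked at random and varied independently. The simulation therefore cannot show how often the list test errs where members vary together.

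Settings planned from the start were other pseudocounts (0.1 and 0.5), no filter or a mean of at least 5 FPKM, scaling by TMM factors, by median ratios or by quantiles, no intensity trend, array weights, the replicate block, leaving out each library, no minimum fold change, limma's treat against a 1.5-fold change, an estimated correlation and fry. Added after the data were seen were limma's voom on the recovered reads (10814 genes with at least 10 reads in at least 3 libraries), with and without the block and with quantile normalization, a loess correction for GC content per library (span 0.3), the block on pairs 2 and 3 alone, and fits of the 9858 protein-coding genes alone, with and without a minimum fold change, the block and the GC correction. GC content and length come from the annotated transcripts and were known for 11899 tested genes. Random lists matched on GC content and expression (10000 per list, from 20 bins of GC content and 5 of expression) and all 10 splits of the libraries into 3 and 3 were also drawn.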

Results

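Kasumi-1 is a human acute myeloid leukaemia line of immature myeloblasts. It carries the t(8;21) translocation, which joins RUNX1 to RUNX1T1. The data hold the mRNA of 6 Kasumi-1 samples, 3 kept with control and 3 with I1 at 0.125 µM, all for 48 h. I1 is a compound known here only by its code name. Levels are FPKM, fragments per kilobase of gene scaled to the total of the library, for 29810 genes. That total was 18204000, 17331000 and 17687000 fragments in control replicates 1 to 3 and 16391000, 16948000 and 16622000 in I1 replicates 1 to 3. A single read in a kilobase of transcript was worth 0.0549 to 0.0610 FPKM.

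The comparison asked which transcripts differed after 48 h with I1. Of 11913 tested genes, 4 rose and 0 fell, and the 4 that rose are small RNA genes with few reads: MIR3685, SNORD18, RNU6-213P and a U6 gene. MIR3685, a microRNA precursor, went from 0.614 ± 0.532 FPKM in control to 11.9 ± 4.03 with I1 (SD, n = 3 each). SNORD18, of a family of small nucleolar RNAs, went from 0.275 ± 0.476 to 6.29 ± 0.398 FPKM. None of the 9858 tested protein-coding genes passed the threshold, which was an adjusted p under 0.05 by limma and a log2 fold change of at least 1 in size. The smallest adjusted p of a protein-coding gene was 0.383, and 0.129 with the replicate number as a block. Tested alone with the block, 3 protein-coding genes passed, SPCS3, CHCHD10 and EVA1B (limma adjusted p = 0.0357, 0.0407 and 0.0407), chosen after their values were seen. A correction for GC content as well took their log2 fold changes from 1.05, -1.52 and -1.03 to 0.65, -1.26 and -0.795 (adjusted p = 0.0392, 0.0858 and 0.0714).

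MIR3685 (ENSG00000265917) lies on chromosome 12 of hg38, from 95309923 to 95309984 on the plus strand, outside any other annotated gene. Its log2 fold change, on the scale of log2(FPKM + 1), was 3.02 with a standard error of 0.307 and an adjusted p of 0.0353. It had 0, 1 and 1 reads in the controls and 9, 11 and 17 with I1. The ratio of depth-scaled reads was 19.7, with an exact 95% interval of 5.09 to 169 that covers counting error only. The other 3 genes fell outside the rule for naming genes and were chosen after their values were seen. SNORD18 (ENSG00000200677; chromosome 15, 90755243 to 90755312, minus strand) lies inside BLM, a DNA helicase gene on the other strand. Its log2 fold change was 2.58 ± 0.243 (SE) at the same adjusted p of 0.0353, from 0, 1 and 0 reads against 7, 8 and 7, a ratio of 23.4 with an exact interval of 3.79 to 968. BLM itself had a log2 fold change of 0.26 and did not pass (adjusted p = 0.552). RNU6-213P (ENSG00000206778; chromosome 16, 15877163 to 15877266, minus strand), a pseudogene of the spliceosomal U6 RNA, lies between exons of FOPNL on the same strand. It had 0 reads in each control and 4, 3 and 4 with I1, 3.91-fold over a floor of 3 reads in the control group, with a mean of 2.12 ± 0.363 FPKM with I1. The exact 95% lower limit of its ratio was 2.67. FOPNL had 7.99 FPKM in control and 11.1 with I1 (adjusted p = 0.467). The U6 gene (ENSG00000283271; chromosome 4, 13051342 to 13051411, plus strand) lies outside other genes. Its reads were 0 in each control and 3, 2 and 3 with I1, 2.84-fold over the same floor, with an exact 95% lower limit of the ratio of 1.82. Both U6 genes had the adjusted p of 0.0353.

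U6 and SNORD18 belong to families of near-identical copies, and whether strand was used in counting is not given in the sources used here, so their assignment to one locus is uncertain. All 4 genes were higher with I1 in 3 of 3 same-numbered pairs. With the replicate number as a block, 2 more small RNA genes passed, also chosen after their values were seen. In simulations with no changed gene the block gave 2.4 calls per simulation, against 0.4 without it. MIR3682 (chromosome 2, 53849122 to 53849205) had 0, 3 and 2 reads against 3, 11 and 11, and its adjusted p was 0.0268 with the block and 0.467 without. A Y RNA gene (ENSG00000239040; chromosome 4, 55412636 to 55412738, inside TMEM165) had 3, 11 and 4 reads against 25, 40 and 37, and its adjusted p was 0.0346 with the block and 0.188 without. With the block and a correction for GC content neither passed (adjusted p = 0.205 and 0.113), and the log2 fold change of MIR3682 went from 1.70 to 1.135 and that of the Y RNA gene from 2.39 to 2.20. By limma 0 genes passed without control replicate 1 or 3 or without any of the I1 replicates (479 to 1173 at an unadjusted p under 0.05), and without control replicate 2 SNORD18 and the Y RNA gene passed (adjusted p = 0.00239 and 0.0117). A correction for GC content left log2 fold changes of 2.90 ± 0.275 (SE) for MIR3685 and 2.29 ± 0.198 for SNORD18, each at an adjusted p of 0.0551, and of 1.40 ± 0.189 for RNU6-213P and 1.52 ± 0.192 for U6, from 1.64 ± 0.164 and 1.71 ± 0.177 before it. Over all alternatives the adjusted p ranged from 0.00384 to 0.472 for MIR3685, from 0.00239 to 0.472 for SNORD18, from 0.0268 to 1.00 for MIR3682 and from 0.0117 to 1.00 for the Y RNA gene.

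**Figure D1:**
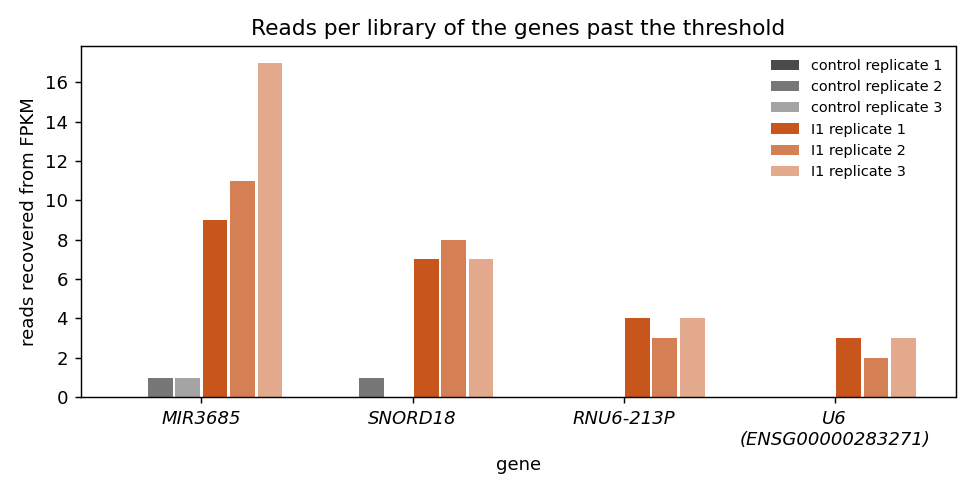
Whole reads per library, recovered from the FPKM values, of the 4 genes that passed the threshold, with control libraries in grey and I1 libraries in orange. Each control library holds 0 or 1 read of each gene, and each I1 library holds 2 to 17.

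Over the 301 tested small RNA genes, these 4 included, with a median of 4 reads per library, the median log2 ratio of depth-scaled reads was 0.57, with medians of 0.71, 0.40 and 0.46 in the 3 same-numbered pairs. Of the 301, 216 were higher and 85 lower. They took 0.0155%, 0.0175% and 0.0192% of the reads of the controls and 0.0227%, 0.0224% and 0.0285% with I1 (exact permutation test, 2-sided p = 0.10, the smallest that 3 against 3 libraries allow). By annotated type on the FPKM scale, median log2 fold changes were 0.56 for 73 small nuclear RNA genes, 0.48 for 80 genes of miscellaneous RNA, which include Y RNAs, 0.26 for 65 small nucleolar RNA genes and 0.19 for 77 microRNA genes, and after a correction for GC content 0.33, 0.27, 0.24 and 0.17. The microRNA genes had pair medians of 0.41, 0.02 and 0.07. Some other types were higher too, with 0.32 for 22 rRNA pseudogenes, 0.29 for 23 sense overlapping genes and 0.24 for 87 sense intronic genes. After the GC correction these were 0.36, 0.06 and 0.03. The 106 unprocessed pseudogenes had -0.03. The 9858 protein-coding genes had a median of 0.02 and took 91.5%, 91.5% and 91.0% of all FPKM in control against 90.5%, 91.0% and 89.7% with I1 (exact permutation test, 2-sided p = 0.10). The libraries were made with a kit for polyadenylated RNA, so these levels do not measure the mature small RNAs.

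Genes typical of this leukaemia and its treatment did not pass the test. Of the 12 genes fixed in advance, 10 were tested and 0 passed by limma, 3 of them (BCL2, SPI1 and RUNX1T1) with an unadjusted p under 0.05. KIT, the receptor of stem cell factor, had 162 ± 15.7 FPKM in control and 196 ± 6.88 with I1, a log2 fold change of 0.28 ± 0.122 (SE) with an adjusted p of 0.467. RUNX1, a transcription factor of blood stem cells, had 31.0 ± 3.29 and 34.5 ± 0.991 FPKM, and RUNX1T1, its fusion partner in these cells, 13.9 ± 1.63 and 17.5 ± 0.811 (log2 fold change 0.32, adjusted p = 0.467). Gene-level values do not separate the fusion transcript from those of the 2 normal genes. KIT, RUNX1, RUNX1T1 and BCL2 had higher values with I1 in 3 of 3 pairs. BCL2, which protects cells from apoptosis, had 4.32 ± 0.252 and 6.36 ± 0.776 FPKM, a log2 fold change of 0.46 ± 0.130 with an adjusted p of 0.467. SPI1, which encodes the myeloid transcription factor PU.1, had 113 ± 9.87 and 88.0 ± 4.95 FPKM, lower in 3 of 3 pairs, with a log2 fold change of -0.36 ± 0.120 and the same adjusted p. SPI1 and BCL2 came under an adjusted p of 0.05 with the replicate block when protein-coding genes were tested alone, at 0.0482 and 0.0496, in a range over the alternatives of 0.0349 to 1.00 and 0.0267 to 1.00. A correction for GC content brought the log2 fold change of SPI1 to -0.13, of KIT to 0.08, of RUNX1T1 to 0.13 and of BCL2 to 0.35, and with the block as well the adjusted p was 0.305 for SPI1 and 0.220 for BCL2.

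The groups overlapped for the remaining tested genes. CD34, a surface marker of blood progenitors, had 39.5 ± 13.2 FPKM in control and 38.3 ± 12.4 with I1, and VEGFA, a growth factor of blood vessels, 7.82 ± 2.18 and 7.58 ± 2.01, each with a log2 fold change of -0.04 and an adjusted p of 0.949. CEBPA, a transcription factor of granulocytes, had 3.97 ± 0.791 and 3.75 ± 0.616 FPKM. MYC had 391 ± 129 and 337 ± 48.9 FPKM, a log2 fold change of -0.18 ± 0.231 (adjusted p = 0.701) that ranged from -0.35 without control replicate 3 and -0.29 without I1 replicate 1 to 0.08 without control replicate 1, and was 0.09 with array weights. CDKN1A, a cell cycle inhibitor induced by p53, had 2.73 ± 1.49 and 2.99 ± 1.70 FPKM, a log2 fold change of 0.09 ± 0.351. It ranged from -0.24 without I1 replicate 3 to 0.39 without control replicate 3 and was -0.33 with array weights. The log2 fold change of CD34 ranged from -0.28 without I1 replicate 1 to 0.21 without control replicate 1, that of VEGFA from -0.25 without control replicate 2 to 0.17 without I1 replicate 2, and that of CEBPA from -0.16 without I1 replicate 2 to 0.07 without control replicate 1. The mature myeloid markers ITGAM and CD14 stayed below the filter on low values. ITGAM, the integrin chain CD11b, had 0.0823 ± 0.0391 and 0.0709 ± 0.0683 FPKM, and CD14, the monocyte receptor, 0.0592 ± 0.0583 and 0.0313 ± 0.0542. Neither reached 1 FPKM in any library, and a fall of either was not detectable at this depth.

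**Figure D2:**
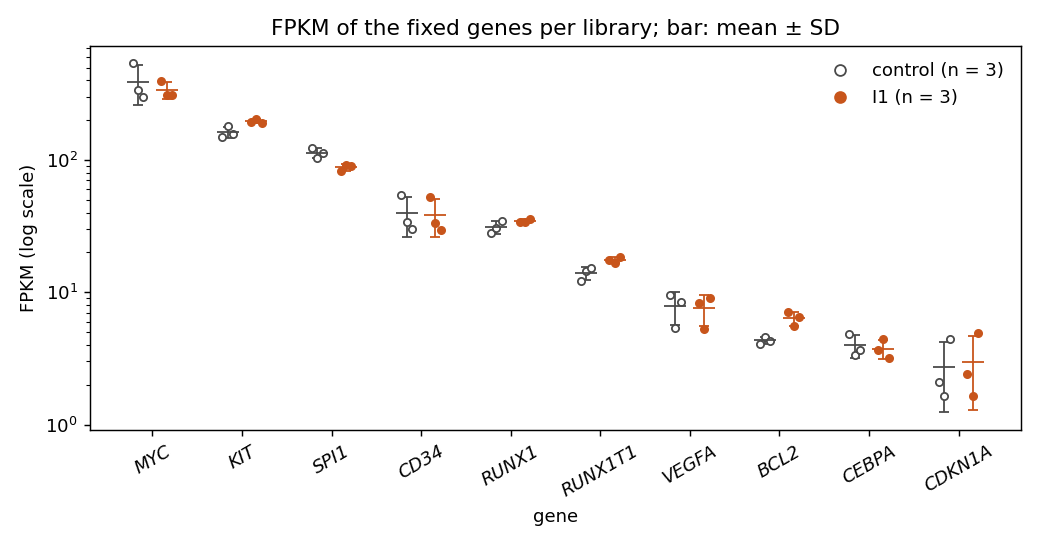
FPKM of the 10 tested genes fixed in advance in each library (log axis), control in open grey points and I1 in orange, with bars for the mean and SD of 3 libraries. The points of control and I1 are interleaved for CD34, VEGFA, CEBPA and CDKN1A, and those of SPI1 are lower with I1 in each pair (113 against 88.0 FPKM on average).

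At the level of gene groups, 5 of 41 gene lists fell against the other tested genes and 1 rose, by limma's camera with a preset correlation between genes. With a correlation estimated from the data 0 of the 41 lists passed (1 at an unadjusted p under 0.05, smallest adjusted p 0.766), and the rotation test fry gave 0 as well (2 unadjusted, smallest adjusted p 0.234). With the preset correlation as many lists passed in 8 of the 10 splits of the libraries into 3 and 3, the real one included, with 19 the highest. The 5 lists that fell hold mature neutrophil genes, myeloid transcription factors, genes of the NF-kB and inflammatory response, nuclear genes of oxidative phosphorylation, and genes of the lysosome and phagocytosis. The list that rose holds DNA repair genes of homologous recombination and the Fanconi anaemia pathway. Of the 816 genes tested within the 41 lists, 0 rose, 0 fell and 816 did not pass, and adjusted over the list alone 0 lists held a member past 0.05.

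Mature neutrophil genes had a median log2 fold change of -0.27 over 10 tested members, 9 of them below 0. The medians were -0.38, -0.25 and -0.32 in the 3 pairs. The list has 27 entries, and the others, ITGAM among them, were not tested. The camera adjusted p was 0.0244, with an adjusted p = 0.766 with an estimated correlation. The most abundant members were GFI1, a repressor needed for granulocyte development, at 142 ± 15.1 FPKM in control and 131 ± 14.3 with I1, and CYBA, a subunit of the phagocyte oxidase, at 86.0 ± 5.12 and 79.1 ± 10.3. Myeloid transcription factors had a median of -0.22 over 14 members, 12 of them below 0 (adjusted p = 0.0244, and adjusted p = 0.766 with an estimated correlation); GFI1 and SPI1 led this list in abundance, and the smallest p adjusted over the list alone was 0.0787. NF-kB and inflammatory genes had a median of -0.25 over 16 members, 13 below 0, at a camera adjusted p of 0.0244 and an adjusted p = 0.927 with an estimated correlation. CCL5, a chemokine, had 40.8 ± 6.55 FPKM in control and 31.1 ± 3.28 with I1, and NFKBIA, an inhibitor of NF-kB, 30.2 ± 12.3 and 25.2 ± 9.07. Both were lower in 3 of 3 pairs, and neither passed over all genes (adjusted p = 0.467 and 0.721).

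Nuclear genes of oxidative phosphorylation had a smaller median of -0.08 over 43 members, 32 below 0, with an adjusted p of 0.0313 and an adjusted p = 0.986 with an estimated correlation. ATP5F1B, a catalytic subunit of ATP synthase, had 511 ± 35.6 and 439 ± 31.6 FPKM, and UQCRH of complex III 146 ± 10.6 and 135 ± 3.07. Lysosome and phagocytosis genes had a median of -0.12 over 25 members, 20 below 0 (adjusted p = 0.0377, and adjusted p = 0.766 with an estimated correlation), and their pair medians were -0.26, -0.08 and -0.01. PSAP, the precursor of lysosomal saposins, had 371 ± 31.6 and 343 ± 15.5 FPKM, and CTSZ, a lysosomal protease, 133 ± 6.79 and 105 ± 16.5. DNA repair genes had a median of 0.25 over 28 members, 23 above 0, with an adjusted p of 0.0446 and an adjusted p = 0.986 with an estimated correlation. Their pair medians were 0.53, 0.10 and 0.12. A correction for GC content brought the DNA repair median to 0.06 and ended the call (adjusted p = 0.372, range over the alternatives 0.00522 to 0.986). It also ended the camera calls of mature neutrophil genes (median -0.17, adjusted p = 0.124), myeloid transcription factors (-0.09, 0.458), NF-kB genes (-0.19, 0.0814) and lysosome genes (-0.05, 0.171). Oxidative phosphorylation kept its call (-0.13, 0.000141).

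One control library stood apart from the rest. On the first principal component, with 52.1% of the variance, control replicate 1 lay at -43.8 and the other 5 libraries between -2.90 and 19.8, and its mean correlation with the others was 0.948 against 0.966 to 0.973. GC-rich genes were higher in it than in the other two controls (Spearman's rho 0.668 across 11899 genes, which are not independent), and GC-rich genes were lower with I1 (rho -0.753; pairs -0.767, -0.477 and -0.574). The 5 lists that fell had median GC contents of 47.9% to 57.6% and the DNA repair list 42.1%. Without control replicate 1 the DNA repair list lost its call (median 0.10, adjusted p = 0.268) while the 5 lists that fell kept theirs, and 13 lists passed in all. The mature neutrophil and myeloid transcription factor lists passed whichever library was left out. NF-kB genes lost the call without control replicate 2 (adjusted p = 0.149) and without I1 replicate 1 (0.0507), oxidative phosphorylation without the same libraries (0.282 and 0.514), lysosome genes without I1 replicate 1 (0.186) or 2 (0.0843), and DNA repair also without I1 replicate 1 (0.0507) or 2 (0.176). The median of myeloid transcription factors was -0.36 without control replicate 2, that of NF-kB genes -0.39 without control replicate 3 and -0.13 without I1 replicate 3, that of oxidative phosphorylation -0.03 without control replicate 2, -0.12 without control replicate 1 and -0.14 without I1 replicate 2, that of lysosome genes -0.07 without I1 replicate 1 and that of DNA repair 0.38 without control replicate 2. Under quantile normalization 0 lists passed, with adjusted p of 0.0911 for 4 of the 6, 0.252 for oxidative phosphorylation and 0.129 for lysosome genes, and medians of the same signs.

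With the replicate number as a block 12 lists passed, 11 lower and 1 higher, among them all 6 above. With the block, none of the 12 passed with an estimated correlation (smallest adjusted p = 0.668) or by fry (0.0857). The 6 others were all lower. Glycolysis genes had a median log2 fold change of -0.16 over 21 members (adjusted p 0.00238 with the block and 0.0606 without), among them GAPDH at 1000.4 ± 182 FPKM in control and 840.2 ± 129.8 with I1 and ENO1 at 599.8 ± 160.5 and 535 ± 142. Primary granule proteins, a list of enzymes and other proteins of immature granulocytes, had a median of -0.15 over 13 members (0.0294 and 0.236). They include MPO, myeloperoxidase, at 8054 ± 1219 and 6712 ± 358 FPKM, and PRTN3, proteinase 3, at 4687 ± 428 and 4173 ± 549.7. Monocyte and macrophage markers had -0.23 over 6 tested members of 24 entries (0.0294 and 0.0832), with CD4 at 35.3 ± 1.28 and 29.9 ± 1.73 FPKM and SIRPA at 18.1 ± 1.46 and 15.6 ± 2.62. Cytokine receptors with JAK and STAT genes had -0.15 over 23 members (0.0294 and 0.0813), with the G-CSF receptor CSF3R at 86.5 ± 25.4 and 73.2 ± 19.7 FPKM. MAPK feedback and immediate early genes had -0.13 over 19 members (0.0294 and 0.0832), with JUNB at 34.2 ± 5.54 and 28.99 ± 3.29. Cytosolic ribosomal proteins had -0.04 over 60 members (0.0242 and 0.126), with RPLP0 at 1304 ± 392 and 1067 ± 204 FPKM and RPS2 at 1248 ± 280.0 and 1143 ± 116. Without the block, these medians moved with the library left out. The glycolysis median ranged from -0.32 without I1 replicate 3 (adjusted p = 3.48e-05) over -0.27 without control replicate 1 (0.00982) and -0.26 without control replicate 2 (0.0137), where the list passed as well, to -0.09 without I1 replicate 2, -0.02 without I1 replicate 1 and 0.04 without control replicate 3 (0.913). The granule median ranged from -0.23 without control replicate 2 to -0.08 without I1 replicate 2 and -0.02 without control replicate 1, and the list passed in none of the 6. The monocyte median ranged from -0.29 without I1 replicate 2 to -0.11 without I1 replicate 1, and the list passed without control replicate 1 (0.0129) and I1 replicate 3 (0.0451). The cytokine receptor median ranged from -0.23 without I1 replicate 1 to -0.02 without control replicate 1 and without I1 replicate 2, and the list passed without I1 replicate 3 (0.0451). The MAPK median ranged from -0.26 without control replicate 2 (0.0137) and -0.22 without I1 replicate 1 to -0.06, -0.05 and -0.05 without control replicate 1, control replicate 3 and I1 replicate 2. The list also passed without I1 replicate 3 (0.0451). The ribosomal list passed as lower without control replicate 2 (median -0.13, 0.0137), control replicate 3 (-0.14, 0.00256) and I1 replicate 1 (-0.14, 0.0122) and as higher without control replicate 1 (0.09, 0.0188). Its median was 0.01 without I1 replicate 2 and 0.05 under quantile normalization. A correction for GC content brought the granule median to -0.06 (-0.055), that of cytokine receptors to -0.06 and that of MAPK genes to -0.04, and with the block as well these 3 lists did not pass (adjusted p = 0.153, 0.295 and 0.484). Over all alternatives the adjusted p of these 6 lists ranged from 3.48e-05 to 0.986 for glycolysis, 0.0294 to 0.986 for granule proteins, 0.0129 to 0.766 for monocyte markers, 0.0283 to 0.766 for cytokine receptors, 0.0137 to 0.986 for MAPK genes and 0.00256 to 0.986 for ribosomal proteins.

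**Figure D3:**
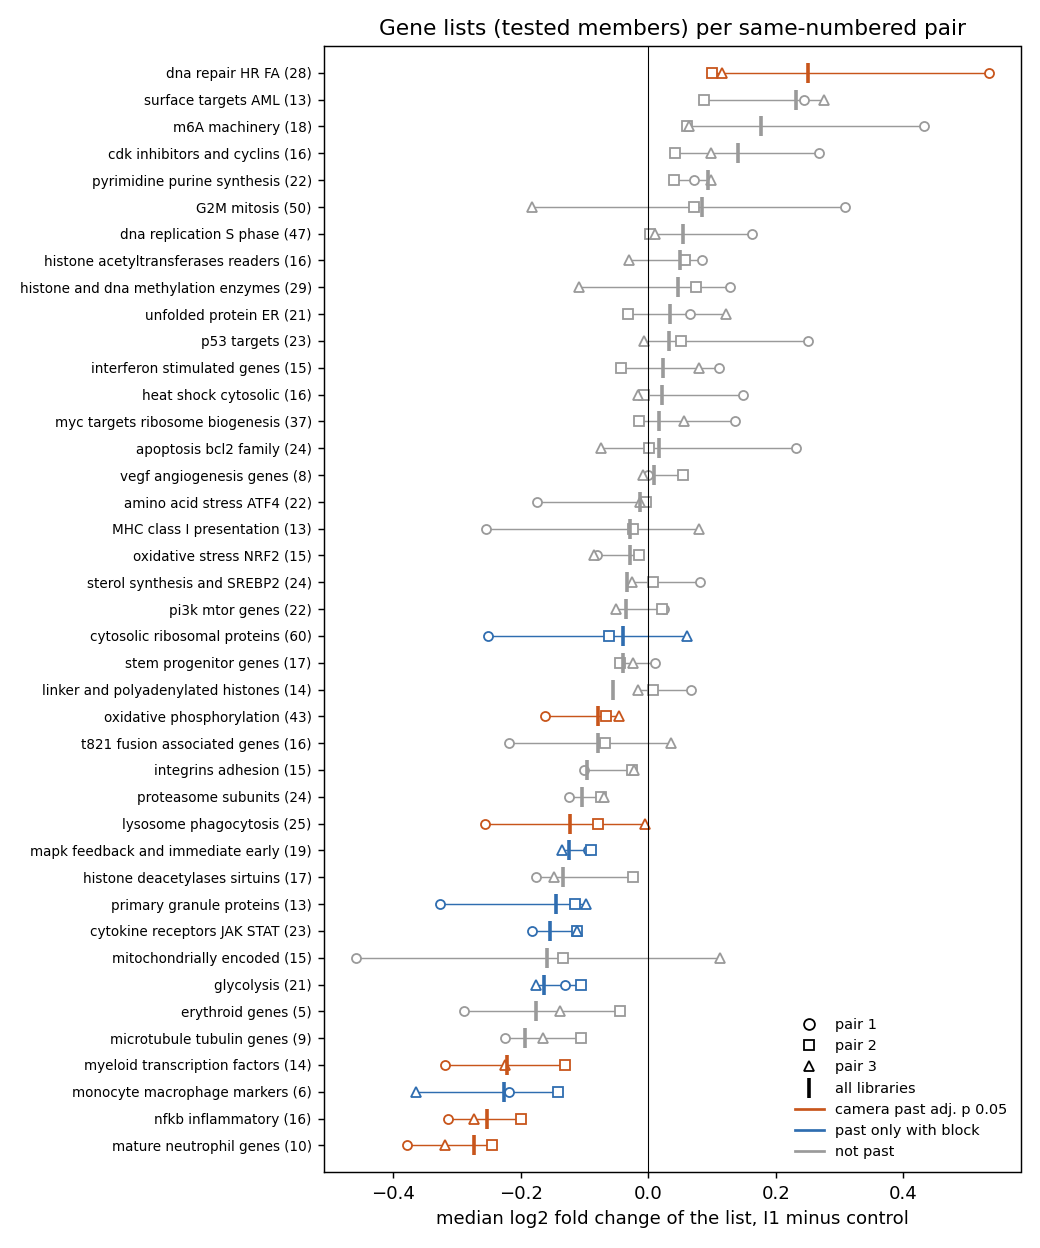
Median log2 fold change, I1 minus control on log2(FPKM + 1), of the tested members of each of the 41 gene lists in all libraries (bars) and in each same-numbered pair (symbols, joined by a line), with member numbers in brackets. The 6 lists past camera's adjusted p of 0.05 are in orange and the 6 past it only with the replicate block in blue. DNA repair has its highest median, 0.53, in pair 1.

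The remaining 29 tested lists passed neither way, and 10 of them passed in at least 1 other setting. Leaving out 1 library turned the sign of the median of 19 of the 29. Stem and progenitor genes had a median log2 fold change of -0.04 over 17 members and genes tied to the t(8;21) fusion -0.08 over 16. The former was 0.13 without control replicate 1 and -0.175 without control replicate 3. LYL1, a transcription factor of the first list, had 118 ± 41.0 FPKM in control and 83.9 ± 11.8 with I1, and JUP, plakoglobin, of the second 91.2 ± 11.9 and 74.4 ± 6.03. Surface proteins used as AML targets had 0.23 over 13 members and passed without control replicate 1 (adjusted p = 0.0273, range over the alternatives 0.0273 to 0.927). Their median was 0.09 without I1 replicate 1, 0.12 without control replicate 3 and 0.015 without a filter. Integrins and adhesion genes had -0.10 over 15 (-0.06 without control replicate 1, -0.006 after GC correction and 0.013 with a mean of at least 5 FPKM). Erythroid genes had -0.18 over 5 members (-0.03 without control replicate 1 and -0.31 without control replicate 3), with TFRC, the transferrin receptor, at 84.9 ± 35.4 and 114 ± 35.1 FPKM. Among proliferation genes, DNA replication had 0.05 over 47 members (-0.04 without control replicate 1 and 0.17 without control replicate 2), with PCNA at 148 ± 32.0 and 149 ± 16.7 FPKM, and G2/M and mitosis 0.08 over 50, with CKS2 at 101 ± 25.4 and 111 ± 18.4. The G2/M list had pair medians of 0.31, 0.07 and -0.18 and passed as lower without control replicate 1 (median -0.06, adjusted p = 0.0188), without I1 replicate 2 (-0.04, 0.0458) and with the block and GC correction (-0.07, 0.0411), in a range of 0.0188 to 0.996. Its highest median was 0.19 without control replicate 2. CDK inhibitors and cyclins had 0.14 over 16 members, with CDK6, a kinase of the G1 phase, at 61.4 ± 17.9 and 94.9 ± 9.19 FPKM (log2 fold change 0.66, adjusted p = 0.467). The log2 fold change of CDK6 was 0.36 after GC correction. This list passed as higher with the block and GC correction (0.0395, range 0.0395 to 0.986). The p53 targets had 0.03 over 23 members (-0.04 without control replicate 2 and 0.15 without control replicate 3) and the BCL2 family with other apoptosis genes 0.02 over 24, with MCL1 at 50.8 ± 9.74 and 57.4 ± 1.89 FPKM. Growth signalling lists were close to 0, with 0.01 for 8 angiogenesis genes and -0.04 for 22 genes of PI3K and mTOR.

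For metabolism and protein turnover, sterol synthesis genes had a median log2 fold change of -0.03 over 24 members. Purine and pyrimidine synthesis had 0.09 over 22 (0.02 without control replicate 1, 0.17 without control replicate 2 and 0.005 after GC correction). The targets of MYC in ribosome biogenesis had 0.02 over 37, with NPM1 at 402 ± 34.5 and 432 ± 23.2 FPKM. Amino acid stress genes driven by ATF4 had -0.01 over 22 members, the unfolded protein response 0.03 over 21 (-0.12 without control replicate 1 and 0.27 without I1 replicate 1), cytosolic heat shock genes 0.02 over 16 (-0.12 without control replicate 1 and 0.175 without control replicate 2) and the oxidative stress genes of NRF2 -0.03 over 15. Proteasome subunits had -0.10 over 24 members and the mitochondrially encoded genes -0.16 over 15, with pair medians of -0.46, -0.13 and 0.11 for the latter. The proteasome list had a camera adjusted p of 0.0606, and 0.0859 with the block, and passed as lower in 8 other settings: with GC correction alone (4.76e-05) and with the block (0.000106), with TMM (0.0375) and median-ratio scaling (0.0393), without a filter (0.0367), and without control replicate 1 (0.000325), I1 replicate 2 (0.00209) or I1 replicate 3 (0.0451), in a range of 4.76e-05 to 0.986. Its median was -0.05 without I1 replicate 1 (0.553) and -0.03 under quantile normalization. The mitochondrially encoded genes passed without control replicate 1 (median -0.23, adjusted p = 0.0436), without I1 replicate 3 (-0.28, 0.00769) and with the block and GC correction (0.0411), in a range of 0.00769 to 0.986. They had a median of 0.045 without I1 replicate 1 (0.503) and of 0 under quantile normalization. Sterol synthesis passed as lower without I1 replicate 3 (-0.25, 0.0167) and with array weights (-0.32, 0.0193) and as higher with the block and GC correction (0.08, 0.0395), in a range of 0.0167 to 0.986. Its median was 0.40 without control replicate 3 and 0.37 without I1 replicate 2. The ATF4 list passed without control replicate 2 (-0.33, 0.0386; range 0.0386 to 0.986) and had medians of 0.153 without control replicate 1 and 0.155 without I1 replicate 2. The NRF2 list passed without I1 replicate 3 (-0.08, 0.0418; range 0.0418 to 0.996) and had a median of 0.095 without I1 replicate 1. Interferon-stimulated genes had 0.02 over 15 members and MHC class I genes -0.03 over 13 (0.19 without control replicate 1), with B2M at 123.5 ± 2.95 and 127 ± 5.81 FPKM. Among chromatin genes the medians were -0.13 for 17 deacetylases and sirtuins, 0.05 for 29 methylation enzymes, 0.05 for 16 acetyltransferases and readers and -0.06 for 14 linker and polyadenylated histone genes. The deacetylase and sirtuin median was -0.065 without control replicate 1 and -0.048 after GC correction. The acetyltransferases and readers passed as higher with the block and GC correction (0.12, 0.0411; range 0.0411 to 0.986). The genes of m6A RNA methylation had 0.18 over 18 members (0.06 without control replicate 1, 0.29 without control replicate 2 and -0.025 after GC correction) and tubulin and microtubule genes -0.19 over 9, and the tubulin list passed without a filter (0.0349), without control replicate 1 (0.0188) and without I1 replicate 2 (0.0450), in a range of 0.0188 to 0.982. Its median was -0.05 without control replicate 3. The median, the mean and the camera test differed in sign for 9 lists, none of which passed in the planned test or with the block alone: G2/M, methylation enzymes, MYC targets, angiogenesis and heat shock had a median and a mean above 0 with a test direction of lower, and for PI3K and mTOR, sterol synthesis, MHC class I and the linker histones the mean lay above 0 and the median and the test below. Another scaling of the libraries turned the sign of 11 of these 29 medians, each of them within 0.05 of 0.

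The 8 lists with fewer than 5 tested members, most of them markers of other cell types, were not tested as groups. The highest mean levels in them were 2.78 FPKM for CD8A among T and NK cell markers, 5.14 for CD79B among B cell markers, 26.7 for EPCAM among fibroblast and epithelial markers, 9.23 for STMN3 among neuronal genes, 18.7 for FLI1 among megakaryocyte genes and 14.96 for GATA2 among eosinophil, basophil and mast cell genes. MHC class II genes reached 73.0 FPKM with CD74, and replication-dependent histones, whose mRNAs mostly lack poly(A) tails, 1.84 with H2AC14.

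Across all tested genes the median size of the log2 fold change was 0.19 and the median standard error 0.162, or 0.118 with the replicate block. Only 76 genes differed by a log2 fold change of 1 or more in size, 3 of them protein-coding. By limma 1140 genes had an unadjusted p under 0.05, 810 of them higher and 330 lower with I1. Chance gives 596 if the 6 libraries are exchangeable, which the pairing of the samples speaks against. With the block 3227 had one, and 1927 with the block and GC correction. The values of the groups did not overlap for 2577 genes, 21.6%, against 10% by chance on the same assumption. With voom on the recovered reads, whose filter on reads leaves out all 4 genes, 0 genes passed, and 1163 had an unadjusted p under 0.05, or 3274 with the block.

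**Figure D4:**
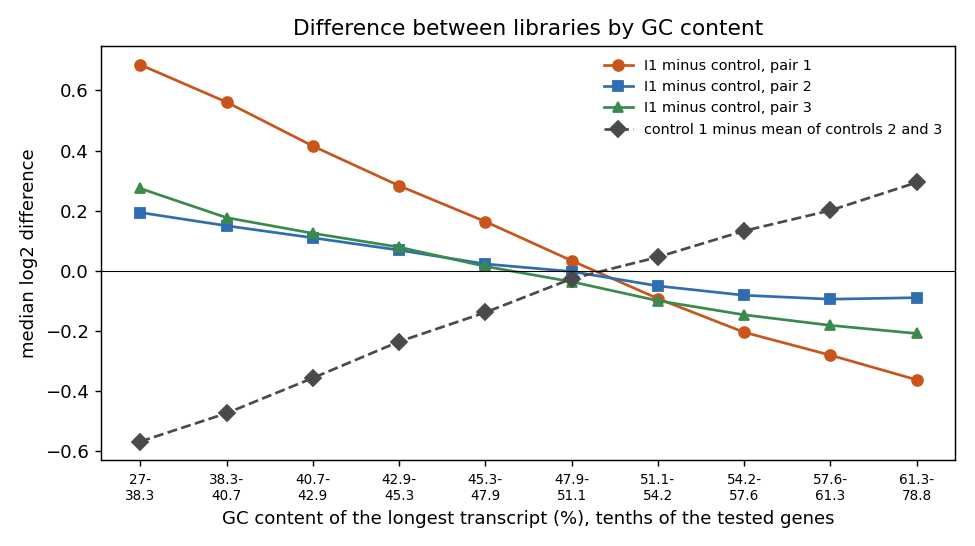
Median log2 difference in 10 bins of the 11899 tested genes with a known GC content, ordered by GC content (percent, x axis), for I1 minus control in each same-numbered pair and for control replicate 1 minus the mean of the other two controls (dashed). The pairs fall with GC content, pair 1 from 0.69 to -0.36, and the dashed line climbs from -0.57 to 0.29.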

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

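Alternatives with voom, with a GC correction, with protein-coding genes alone, with pairs 2 and 3 alone and with the block combined with another choice were chosen after the result was seen; the others were planned. The planned count tests were not run, because the table holds no counts. Against 4 genes and 6 lists by limma, the counts of genes past the threshold were 0 with pseudocounts of 0.1 and 0.5, without a filter and with a mean of at least 5 FPKM (1 list; 685 to 1726 genes at an unadjusted p under 0.05 in these 4 settings), 0 by treat against a 1.5-fold change (37 at an unadjusted p under 0.05), 2 with quantile normalization (0 lists) and 14 with array weights. TMM and median-ratio scaling kept the 4 genes and the 6 lists and added 1 list, and a fit without an intensity trend gave 4 genes and 5 lists. Array weights gave 5 lists, 2 of the 6 among them. With these weights NF-kB (camera adjusted p = 0.192), oxidative phosphorylation (0.153), lysosome (0.0695) and DNA repair genes (0.0800) lost the call. Leaving out a library gave 0 to 2 genes (2 without control replicate 2) and 3 to 14 lists (3 without I1 replicate 1, 14 without I1 replicate 3, 13 without control replicate 1). An estimated correlation and fry gave 0 lists, with and without the block.

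With the replicate block 6 genes and 12 lists passed, and the block changed no other call of a named gene or list. By voom 0 genes and 3 lists passed, with the block 0 genes and 12 lists (1163 and 3274 genes unadjusted), and with quantile normalization as well 35 genes (1047 by adjusted p alone, and 0 of those tested when GC content was corrected too). GC correction left 0 genes (588 unadjusted) and 2 lists (1 of the 6), and with the block 1 gene, MIR3685, and 12 lists, 3 of the 6 among them. Pairs 2 and 3 alone gave 5 genes, 2 of the 4 among them, and 5 lists. Among protein-coding genes alone 0 passed (1042 at an unadjusted p under 0.05), 3 with the block, 622 with the block and no minimum fold change and 12 when GC content was corrected too. The median of the cytosolic ribosomal proteins ranged from -0.14 without control replicate 3 (adjusted p = 0.00256) to 0.09 (0.088) without control replicate 1, where it was called higher; in the block with GC correction sterol synthesis genes had a median of 0.08 (0.084) and an adjusted p of 0.0395. The cause was not tested, except that the filter of voom leaves none of the 4 genes in the test, that a mean of at least 5 FPKM leaves only MIR3685 and that a left-out library leaves fewer samples. Of 2143 values of named genes under the alternatives 2061 kept their side of the threshold, 51 lost the call and 31 gained one; of 1019 list values 897 kept it, 64 lost and 56 gained a call and 2 passed in the other direction. The direction differed from the planned test in 133 of the gene values and 121 of the list values, these 2 included. With 0 or 1 read per control library, the depth limits the folds of the 4 genes to their counting intervals.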

Other observations

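The tests with the block on protein-coding genes, those for a GC trend between libraries and for a response to I1, for counting error, for the GC content of the small RNA genes and of the lists, for a surrounding gene on the other strand, and the split test for genes were chosen after the result was seen; those for gene length, for small RNA genes as a class, for a surrounding gene on the same strand and the split test for lists were not. Among protein-coding genes alone, with the replicate block, a GC correction and no minimum fold change, 9 genes were lower and 3 higher with I1 at an adjusted p under 0.05 by limma, and 9 of the 12 also passed without the GC correction. The genes were chosen after their values were seen. CMTM8 fell from 10.6 ± 2.35 FPKM in control to 5.15 ± 0.0412 with I1 (SD, n = 3 each), a GC-corrected log2 fold change of -0.85 with an adjusted p of 0.0268. EBPL, related to a sterol isomerase, fell from 53.3 ± 9.48 to 27.5 ± 4.84 FPKM (-0.99, 0.0392), and GSN, the actin-severing protein gelsolin, from 58.5 ± 5.59 to 41.8 ± 5.39 (-0.49, 0.0436). ID1, an inhibitor of basic helix-loop-helix factors, went from 27.9 ± 5.41 to 17.6 ± 3.21 FPKM (-0.48, 0.04999), the Wnt receptor FZD2 from 8.74 ± 2.66 to 4.57 ± 0.420 (-0.55, 0.0476) and NPW, the precursor of neuropeptide W, from 164 ± 51.3 to 84.1 ± 16.1 (-0.63, 0.0476). SS18L2 rose from 10.4 ± 1.55 to 16.9 ± 1.03 FPKM (0.55, 0.0268), DCK, deoxycytidine kinase, which activates cytarabine, from 9.28 ± 3.26 to 16.5 ± 3.12 (0.48, 0.0392), and SPCS3, a subunit of the signal peptidase, from 15.9 ± 8.04 to 31.4 ± 8.29 (0.65, 0.0392). Each of these 9 genes moved one way in 3 of 3 pairs. Their adjusted p was 0.0357 to 0.0407 without the GC correction, 0.129 to 0.140 with the block over all genes, and 0.383 to 0.467 in the planned test, where none passed.

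CENPW, CXCL8 and NBDY passed only after the GC correction. Without it, and without a minimum fold change, 622 protein-coding genes passed with the block, 470 higher with a median GC content of 37.7% and 152 lower with a median of 60.6%, against 47.9% for all. Their median size of log2 fold change was 0.51. In the 3 other splits that part all 3 pairs, the same fits gave 0, 0 and 0 genes in place of 622, and 0, 0 and 0 in place of 12. Each of these splits exchanges the members of 1 pair, so that a difference common to all pairs is diluted in them, and 4 such splits are too few to exclude chance.

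GC-rich genes were lower with I1 and GC-poor genes higher (rho -0.753 over 11899 genes; median log2 fold change 0.39 in the bin with the lowest GC content and -0.22 in that with the highest). Gene length is argued against, since the rank correlation with exon length given GC content was 0.032. GC-dependent recovery that varies between libraries is a candidate explanation, since control replicate 1 differed from the other two controls at a rho of 0.668 without any treatment. A response to I1 cannot be told apart from it: the weakest of the 3 pairs still had a rho of -0.477, but libraries of one treatment also differed, at 0.249 for I1 replicate 1 against the other two and -0.287 for control replicate 2 against 3. The splits that part all pairs had a rho of -0.602, -0.725 and -0.296.

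Of the 4 small RNA genes that passed, MIR3685 and U6 lie outside other genes. Reads of a surrounding gene stay open for RNU6-213P and SNORD18. Small RNA genes inside another gene on the same strand had a lower median log2 ratio than genes outside any other gene (0.46 against 0.61). The difference of -0.149 lay within its spread of 0.194, and a median of many genes cannot place the reads of a single locus. Genes inside another gene on the other strand had a median of 0.78 (difference 0.175, spread 0.222), and the use of strand in counting is not given in the sources used here. After GC correction the 4 genes had a median log2 fold change of 1.90 (1.904) against 2.14 before, at standard errors of up to 0.275 and 0.307. The correction removes only the trend of all tested genes, whose median reached 0.39 in the bin with the lowest GC content. It could not have taken folds of this size to 0, so it does not decide on GC content as the source for such short genes. The calls of the 4 genes ended. For RNU6-213P and U6 the folds were smaller and the standard errors larger (1.40 ± 0.189 from 1.64 ± 0.164 and 1.52 ± 0.192 from 1.71 ± 0.177). Their unadjusted p by limma was 0.000105 and 6.78e-05. For MIR3685 and SNORD18 it was 9.25e-06 and 4.72e-06 against 1.01e-05 and 5.92e-06 before. Fewer genes had so small a p, which left an adjusted p of 0.0551. With the block as well, MIR3685 passed (adjusted p = 0.0227). Counting error is argued against for MIR3685 and SNORD18, whose largest exact binomial p was 1.7e-06 against a limit of 4.2e-06 over all genes. That test takes reads as independent and rightly placed, and the locus of the SNORD18 reads is uncertain. Counting error remains open for RNU6-213P and U6, where the exact binomial p reached 0.00302. A rise of small RNA genes as a class, with a median log2 ratio of 0.567, is a candidate explanation. The exact 95% lower limits of the ratios of MIR3685 and SNORD18, 5.09 and 3.79, lie above a rise of that median size. Both genes were picked for their rises in these same data, and the limits make no allowance for that. The limits therefore do not decide whether the class rise is the whole source or a part. Whether the class rise lies in the cells or in the recovery of short or nonpolyadenylated RNA was not tested. Of the 301 genes, 198 lie inside another gene on the same strand and 71 inside one on the other strand. Reads of surrounding transcripts therefore stay open for the class as well, though the 31 genes outside any other gene had a median log2 ratio of 0.61. The real split gave 4 genes and the highest of the other 9 splits 1, and 10 splits are too few for a share under 0.05. With the block the real split gave 6 and the 3 others that part all pairs 0. Simulations with no changed gene and no pairing gave 2.4 calls with the block.

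The medians of the 6 gene lists were set against 10000 random lists matched on GC content and expression. They lay at percentile 0.3 for mature neutrophil genes, 1.1 for oxidative phosphorylation and 0 for NF-kB genes (matched on expression alone 0, 18.1 and 0), lower than in most random lists of like GC content. They lay at 13.9 for myeloid transcription factors, 20.5 for lysosome genes and 87.2 for DNA repair (0.1, 5 and 99.8), for which GC content may account. The 6 lists were chosen for their shifts in these same data, and members of random lists need not vary together. The percentiles therefore do not decide whether GC content together with chance is the whole source. With the GC correction alone oxidative phosphorylation passed with a median of -0.13 from -0.08 (adjusted p = 0.000141), while mature neutrophil genes, with a median of -0.17 from -0.27, and NF-kB genes, with -0.19 from -0.25, lost the call with smaller medians (0.124 and 0.0814), as did myeloid transcription factors with -0.09 from -0.22 (0.458), lysosome genes with -0.05 from -0.12 (0.171) and DNA repair with 0.06 from 0.25 (0.372). With the block and the GC correction together the adjusted p was 0.0302 for neutrophil genes, 0.000555 for both NF-kB and oxidative phosphorylation, 0.295, 0.0685 and 0.207 for the other three, in ranges over the alternatives of 0.00238 to 0.766, 0.000554 to 0.927, 0.000141 to 0.986, 0.00380 to 0.766, 0.00215 to 0.776 and 0.00522 to 0.986. In 8 of the 10 splits of the libraries as many lists passed, the real one with 6 and the highest of the others with 19, which set control replicate 1 with I1 replicates 1 and 3 against the rest and points to a structure of the samples. With the block the real split gave 12 lists and the 3 others that part all pairs 9, 2 and 5, so a response of these genes to I1 stays open, untested apart from this.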
